A study of Saccharomyces cerevisiae and Saccharomyces paradoxus and Saccharomyces cerevisiae x Saccharomyces paradoxus with 12 samples.

How the data were processed

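RNA-seq, which measures mRNA abundance, and ribosome profiling (Ribo-seq), which sequences the mRNA pieces that ribosomes protect, were analysed in diploid Saccharomyces cerevisiae (strain GSY83), diploid S. paradoxus (GSY82) and their F1 hybrid (GSY88). Each strain gave 2 libraries per assay, so that 12 libraries fell into 6 groups with n = 2. Cells grew in rich glucose medium and received cycloheximide, a drug that stalls ribosomes, before extraction, per the labels' protocols. The labels do not say whether the 2 replicates of a group came from separate cultures, so the p-values below measure only the spread between these samples.

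The tools CASAVA 1.8, cutadapt 1.2.1, Bowtie 0.12.8 and bedtools 2.17.0 and the build sacCer3 were used, per the submitters' processing notes, while the role and settings of each tool and the name of the S. paradoxus assembly are not given in the sources used here. The deposited values were counts of reads per gene, for 5226 genes in 16 columns, with 8 parental columns and 8 columns that hold the S. cerevisiae or the S. paradoxus allele of a hybrid library, per the file headers. The parental columns were headed "Mix", a word whose meaning is not given in the sources used here. The deposited coordinate tables held start and end positions, with starts counted from 0, of 5474 genes in each species, of which 248 were absent from the count table. Per the submitters' processing notes the S. cerevisiae positions are in sacCer3, and 5325 of the 5332 genes that could be compared lay at their R64 position. A locus tag of the R64 gene table matched 5183 of the IDs, and 43 had no match and kept their ID. The library preparation kept the sense strand per the labels, while the use of strand in counting is not given in the sources used here.

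Depth was 6116133 to 8910405 counts per column. The totals of the S. cerevisiae and the S. paradoxus column of the same assay and number lay within 0.18% of each other, so any difference in depth between the species was no longer visible in the table. In 12 of the columns no gene had 0 counts and many had 1, while the 4 S. cerevisiae RNA-seq columns held 15, 18, 37 and 23 genes at 0. The ortholog coding lengths were equal for 3250 genes and differed by over 10% for 158. Counts of gene pairs with near-identical sequence, such as duplicated ribosomal protein genes, TDH1 and TDH2, SSA1 and SSA2, HEF3 and YEF3, PHO3 and PHO5, ENO1 and ENO2, and the silent and active mating-type copies, are uncertain, as are those of overlapping and antisense genes. No genome sequence of either species was at hand. Ambiguous mapping between alleles or paralogs could therefore not be checked for any gene, ADH1 and ADH2 included.

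Differential tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10 (5158 genes tested), group means over all 16 columns, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. The fit had 8 residual degrees of freedom, prior degrees of freedom of 5.26 and a common biological coefficient of variation of 0.179. Log2 values are S. cerevisiae minus S. paradoxus, between the parents or between the 2 alleles in the hybrid. Translation efficiency is the Ribo-seq ratio minus the RNA-seq ratio on the log2 scale, and the parental ratio minus the allelic ratio was tested as an interaction. For the total output of the hybrid the alleles were summed, giving 12 libraries and 5159 genes tested. A gene was outside the parental range when it passed against each parent in the same direction.

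The 2 alleles of a hybrid library are paired by construction, and their deviations from the replicate mean correlated by 0.84 in RNA-seq and 0.52 in Ribo-seq. Hybrid results are therefore also given with the library as a block in the hybrid columns alone. That fit has a term for each library and leaves fewer residual degrees of freedom than the main fit, so its counts and p-values rest on less replication. A parental fit without the hybrid columns was planned as an alternative. A limma 3.58.1 voom fit over all columns with a random library effect, whose within-library correlation was 0.733, was added after the values were seen.

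Gene lists fixed beforehand were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists within a comparison. The lists were cytosolic ribosomal proteins, ribosome biogenesis, mitochondrial ribosomal proteins, oxidative phosphorylation, the tricarboxylic acid and glyoxylate cycles, glycolysis and fermentation, hexose transporters and glucose sensing, ergosterol synthesis, amino acid synthesis, sulfur and methionine metabolism, chaperones and heat shock, oxidative stress, the proteasome, translation factors, aminoacyl tRNA synthetases, the vacuolar ATPase, iron and copper uptake, phosphate and zinc uptake, thiamine and biotin synthesis, the cell wall, galactose and maltose use, stationary-phase and glucose-repressed genes, histones, haploid and mating genes, meiosis and sporulation, and strain marker genes often deleted in laboratory strains. Haploid and mating genes and sporulation genes stand for cells other than vegetative a/alpha diploids.

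Noise-free variances of log2 ratios across genes were covariances between the ratio of replicate 1 and that of replicate 2, on TMM-scaled counts scaled to library size (CPM) plus 1, for genes with a mean of at least 10 counts in each group, with 95% intervals from 1000 bootstrap draws of genes. Genes are not independent replicates, so these intervals and the correlations across genes describe these libraries. Library medians, correlations and figures were made with R and with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.

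Genes were named by a fixed rule. It took the 5 largest changes in each direction that passed, with a mean of at least 10 counts in each group and both replicates of one side above both of the other. It took the 3 members with the smallest p of each list that passed, and the first member of each other list with at least 3 members that passed. For the hybrid totals it took the 3 genes in each direction farthest from the nearer parent. A marker gene of 1 strain, at no more than 3 counts in every library of the other, would also have been named, and 0 genes met this. Gene lists, comparisons, thresholds and the naming rule were chosen before the data were examined, and genes or tests chosen later are named as such.

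Each procedure was tested on simulated counts with known changes in 200 genes. For parental mRNA (5139 genes) 10.4% of 1.5-fold, 61.2% of 2-fold and 95.5% of 4-fold changes were recovered. Translation efficiency in the parents gave 0%, 19.4% and 80.3% (5145 genes), and in the alleles 1.49%, 13.4% and 84.8%. Allelic mRNA gave 5.97%, 56.7% and 92.4% (5139 genes). With the library block it gave 68.7%, 100% and 98.5% (5123 genes), in other simulated counts. Those had a fixed dispersion for all genes and a library effect shared by both alleles, so these shares do not compare the fits. The difference between the parental and the allelic mRNA ratio gave 1.49%, 11.9% and 83.3% (5144 genes), and totals outside the parental range 4.48%, 61.2% and 100% (5150 genes). Alternatives were relative log expression (RLE) scaling, DESeq2 1.42.0, no filter, mean counts of at least 50 or 200, thinned counts, a minimum fold of 1.5, zeros raised to 1, an offset for ortholog length, shared scaling, pseudocounts of 0.1 and 5, plain variances, replicate and library blocks, each library left out, camera with an estimated correlation, and fry. Counts simulated with the called translation efficiency differences at random genes or with the hybrid at the mean of its parents (20 draws each), removal of the trend on coding length, list tests with the library block, and list medians with members of no more than 3 counts per library set to that floor, were added after the values were seen.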

Results

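RNA-seq and ribosome profiling libraries of the budding yeasts S. cerevisiae and S. paradoxus and of their F1 hybrid were compared to ask how mRNA abundance, ribosome occupancy and translation efficiency differ between the species and between their alleles in 1 cell. Each of the 6 groups of strain and assay held 2 libraries, 12 in all, and the hybrid libraries were counted for each allele. The 16 columns held 6116133 to 8910405 counts each over 5226 genes. Replicates correlated across genes by 0.993 for S. cerevisiae RNA-seq, 0.979 for S. paradoxus RNA-seq, 0.992 for the Ribo-seq of either parent, 0.990 for the Ribo-seq of the hybrid alleles, and 0.951 and 0.950 for the RNA-seq of the S. cerevisiae and the S. paradoxus allele. Values are given in counts scaled to library size (CPM) as mean ± SD with n = 2, and positions are in S. cerevisiae R64 (sacCer3) coordinates.

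In rich glucose medium S. cerevisiae held more mRNA than S. paradoxus of genes that are shut off by glucose or switched on in stationary phase. This held for them as a list, and not every member was called. Phosphate and zinc uptake genes taken as a list were also higher in S. cerevisiae (9 higher and 2 lower of 17). Lower in S. cerevisiae, as lists, was the mRNA of genes that build ribosomes, of the ergosterol pathway, of the respiratory chain and of enzymes that charge tRNAs. Not every member of these lists was called either, and single members of the ergosterol and respiratory chain lists were higher. As lists these differences passed camera at a preset correlation and not with an estimated one, with adjusted p = 0.444 with an estimated correlation for ribosome biogenesis, oxidative phosphorylation and phosphate and zinc uptake, 0.052 for ergosterol synthesis, 0.534 for the synthetases and 0.572 for stationary-phase genes. The largest difference was at ADH2, which encodes the glucose-repressed alcohol dehydrogenase that consumes ethanol. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2245 of 5158 genes differed (43.5%), of which 1129 were higher and 1116 lower in S. cerevisiae and 1122 differed at least 2-fold. The median size of a called difference was 1.00 on the log2 scale. Without the hybrid columns in the fit 2959 genes passed, and without S. cerevisiae RNA-seq replicate 2 1352 passed.

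ADH2 (chromosome XIII, 873291 to 874337) had 374 ± 19.6 CPM in S. cerevisiae and 6.95 ± 1.21 in S. paradoxus, a log2 ratio of 5.75 (SE 0.30, adjusted p = 6.9e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for each gene below). SPL2 (VIII, 374654 to 375100), which restrains low-affinity phosphate transport, had 212 ± 2.77 and 5.17 ± 2.38 CPM and a ratio of 5.36 (SE 0.32, adjusted p = 1.69e-07). PHM8 (V, 225889 to 226854), a phosphatase gene induced when phosphate is scarce, had a ratio of 4.88 (SE 0.37, adjusted p = 1.59e-06). HSP31 (IV, 1501447 to 1502160), a methylglyoxal-detoxifying stress gene, had 4.89 (SE 0.35, adjusted p = 1.08e-06), and the dehydrogenase gene BDH2 (I, 33448 to 34701) 5.02 (SE 1.07, adjusted p = 0.0023). In the other direction the ferric reductase gene FRE4 (XIV, 739951 to 742110) had 12.2 ± 0.766 CPM in S. cerevisiae and 328 ± 34.8 in S. paradoxus (-4.75, SE 0.42, adjusted p = 5.8e-06). ECM13 (II, 136688 to 137461) had a ratio of -4.52 (SE 0.41, adjusted p = 5.98e-06). RTA1 (VII, 918512 to 919465) had 11.3 ± 3.11 and 241 ± 54.4 CPM (-4.42, SE 0.37, adjusted p = 3.3e-06). The high-affinity copper transporter gene CTR3 (XII, 947253 to 947978) had 7.59 ± 2.90 and 112 ± 8.38 CPM (-3.88, SE 0.29, adjusted p = 1.31e-06). PRM7 (IV, 381985 to 384081), whose coding length is 2097 bases in S. cerevisiae and 1596 in S. paradoxus, had a ratio of -3.70 (SE 0.54, adjusted p = 0.000186).

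Among the 26 lists, 9 passed the camera test at the preset correlation. With an estimated correlation among genes none of the 9 passed: adjusted p = 0.444 with an estimated correlation for ribosome biogenesis, translation factors, oxidative phosphorylation and phosphate and zinc uptake, 0.052 for ergosterol synthesis, 0.668 for cytosolic ribosomal proteins and thiamine and biotin synthesis, 0.572 for stationary-phase genes and 0.534 for the synthetases. Ribosome biogenesis genes had a median ratio of -1.24, with 0 higher and 43 lower of 48 (45 adjusted over the list alone, camera adjusted p = 6.47e-14). NSR1, a nucleolar protein gene of pre-rRNA processing, had 354 ± 30.4 CPM in S. cerevisiae and 1696 ± 19.1 in S. paradoxus (-2.26), and the processing genes UTP5 (-1.60) and SPB4 (-1.39) were also lower. Cytosolic ribosomal protein genes had a median of -0.58, with 1 higher and 56 lower of 116 (63 adjusted over the list alone, 3.26e-07). Without S. paradoxus RNA-seq replicate 1 this median was -0.33. The S. paradoxus RNA-seq replicates themselves differed by a median of -0.44 in this list (replicate 2 minus replicate 1). RPL7A (-1.62), RPL15B (-2.55) and RPL35A (-1.25) were lower, and their counts are uncertain because near-identical duplicates share sequence. Translation factors (0 higher and 24 lower of 37, 26 adjusted over the list alone, median -0.67, 5.54e-06) included HYP2 (-1.84), the gene of the hypusinated factor eIF5A, NIP1 (-1.54) of eIF3, and TIF6 (-0.96). Aminoacyl tRNA synthetase genes (0 higher and 12 lower of 17, 13 adjusted over the list alone, median -0.65, 0.000292) included the leucyl enzyme gene CDC60 (-1.63), the threonyl enzyme gene THS1 (-0.97) and the glycyl enzyme gene GRS1 (-0.67).

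Ergosterol synthesis genes (1 higher and 18 lower of 24, 20 adjusted over the list alone, median -1.09, camera adjusted p = 3.10e-09) included CYB5, the cytochrome b5 gene, at 45.8 ± 3.07 and 297 ± 1.35 CPM (-2.70), ERG26 (-1.49) and ERG28 (-2.22). Oxidative phosphorylation genes (1 higher and 21 lower of 32, 24 adjusted over the list alone, median -0.76, 8.99e-06) included the cytochrome c gene CYC1 at 48.5 ± 5.84 and 296 ± 76.5 CPM (-2.61), the Rieske protein gene RIP1 (-1.40) and COX13 (-1.68). Phosphate and zinc uptake genes (9 higher and 2 lower of 17, 11 adjusted over the list alone, median 1.27, 1.25e-05) included the high-affinity phosphate transporter gene PHO84 (XIII, 24037 to 25800) at 1972 ± 52.6 and 206 ± 21.7 CPM (3.26), and VTC4 (2.04), the polyphosphate polymerase gene. Stationary-phase and glucose-repressed genes (13 higher and 0 lower of 24, 16 adjusted over the list alone, 0.000124) had a median of 2.21, or 1.78 with 2 members set to a floor of 3 counts per library. They included the trehalase gene NTH1 at 232 ± 2.09 and 11 ± 1.56 CPM (4.39) and the cell surface gene SPI1 (3.74). Thiamine and biotin synthesis genes (4 higher and 0 lower of 15, 4 adjusted over the list alone, median 0.66, 0.0322) included the biotin synthase gene BIO2 (1.91), the biotin transporter gene BIO5 (1.8) and PHO3 (2.81), a phosphatase gene whose coding length is 1404 and 960 bases in the 2 species and which shares sequence with PHO5. The thiamine and biotin list did not pass without S. paradoxus RNA-seq replicate 2 (camera adjusted p = 0.105). BIO5 did not pass without S. paradoxus RNA-seq replicate 1 (0.122 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), nor did the histone gene HTA1 without replicate 2 (0.104).

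The other 17 lists did not pass camera, though single members stood out. Iron and copper uptake genes (3 higher and 9 lower of 23, camera adjusted p = 0.0547) included CTR3, and meiosis and sporulation genes (12 higher and 2 lower of 27, 0.0547) included ZIP2 (2.34), a synapsis gene. Oxidative stress genes (11 higher and 2 lower of 19, 0.110) included the peroxidase gene GPX1 (2.62), and chaperones and heat shock genes (7 higher and 14 lower of 28, 0.118), whose median was -0.62 and mean -0.06, included HSP31. Tricarboxylic acid and glyoxylate cycle genes (5 higher and 1 lower of 13, 0.126) included the isocitrate lyase gene ICL1 (3.33), and sulfur and methionine genes (9 higher and 4 lower of 24, 0.227) the homocysteine synthase gene MET17 (2.49). MET17 was also first among the strain marker genes (4 higher and 1 lower of 7, 0.126). The mitochondrial ribosomal protein list (5 higher and 17 lower of 72, 0.132) was filled by gene symbol alone. Its first member, MRP8 (1.69), ran against most called members, and its symbol does not show that it encodes such a protein. Histone genes (3 higher and 0 lower of 8, 0.208) included HTA1 (0.58). Glycolysis and fermentation genes (6 higher and 6 lower of 22, 0.700), with a median of -0.18 and a mean of 0.25, included the enolase gene ENO1 (2.57), whose counts are uncertain beside ENO2. Amino acid synthesis genes (14 higher and 14 lower of 49, 0.802) included the ornithine carbamoyltransferase gene ARG3 (-2.87). Haploid and mating genes (7 higher and 4 lower of 20, 0.720), which a/alpha diploids repress, included the meiosis repressor gene RME1 (4.02). Cell wall genes (1 higher and 4 lower of 25, 0.460) included the mannoprotein gene TIR3 (1.8), and galactose and maltose genes (2 higher and 2 lower of 9, 0.950) GAL7 (2.46). Hexose transporters (0 higher and 1 lower of 7, 0.244), the vacuolar ATPase (0 higher and 2 lower of 13, 0.332) and the proteasome (1 higher and 1 lower of 30, 0.950) had few called members. For the proteasome the median was 0.02 and the mean -0.00.

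Ribosome occupancy of the parents followed mRNA for most genes, and where mRNA and translation efficiency both differed they mostly ran in opposite directions. The lists of tRNA synthetase, chaperone, glycolysis and sulfur metabolism genes had higher translation efficiency in S. cerevisiae by camera at a preset correlation, with 5 of 17, 6 of 28, 5 of 22 and 4 of 24 members called, and did not pass with an estimated one, at adjusted p = 0.411 with an estimated correlation for each. Several genes with little or no mRNA difference, such as YOL014W, FLR1 and TEC1, had far fewer ribosomes in S. cerevisiae. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1702 genes differed in occupancy (928 higher, 774 lower, 870 at least 2-fold) and 179 in translation efficiency (104 higher, 75 lower, 156 at least 2-fold, median size 1.54). Parental libraries alone gave 2336 and 572. Without 1 library, translation efficiency calls ranged from 56 (without S. cerevisiae RNA-seq replicate 2) to 722 (without hybrid RNA-seq replicate 2), and each library but S. paradoxus RNA-seq replicate 2 moved the count over 1.5 times when left out. The balance of higher and lower turned to 21 and 36 without S. cerevisiae RNA-seq replicate 1, 20 and 36 without replicate 2, 26 and 33 without S. cerevisiae Ribo-seq replicate 1, 29 and 34 without S. paradoxus Ribo-seq replicate 2, 42 and 44 without S. paradoxus RNA-seq replicate 1 and 42 and 47 without either hybrid Ribo-seq library. Occupancy calls fell to 1027 without S. cerevisiae Ribo-seq replicate 2 and to 1082, 1046 and 1099 without S. cerevisiae Ribo-seq replicate 1 or S. paradoxus Ribo-seq replicate 1 or 2.

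The largest gain in translation efficiency in S. cerevisiae was at KNS1 (XII, 105686 to 107899), a LAMMER-family protein kinase gene, whose log2 ratio was -1.91 in mRNA and 1.83 in occupancy, and 3.74 in translation efficiency (SE 0.39, adjusted p = 0.000186 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for the genes that follow). Its mRNA was 19.7 ± 0.951 and 73.9 ± 19.6 CPM and its occupancy 40.6 ± 0.645 and 11.5 ± 3.85. The small heat shock protein gene HSP26 (3.04, SE 0.72, adjusted p = 0.0382), the aquaglyceroporin-like gene AQY3 (2.91, SE 0.68, 0.0357), YPL216W (2.66, SE 0.35, 0.00127) and HEF3 (2.61, SE 0.41, 0.00423), a paralog of the elongation factor gene YEF3 whose counts are uncertain for that reason, followed. YOL014W (XV, 299693 to 300067) had 65.0 ± 10.5 and 60.2 ± 2.71 CPM in mRNA but 7.05 ± 0.0631 and 79.1 ± 8.43 in occupancy, a translation efficiency ratio of -3.60 (SE 0.28, adjusted p = 1.57e-05). FLR1, a multidrug transporter gene, had 84.5 ± 5.37 and 86.7 ± 2.37 CPM in mRNA and 4.05 ± 1.05 and 41.9 ± 11.4 in occupancy (-3.36, SE 0.47, 0.00204). TEC1, the transcription factor gene of filamentous growth (-3.56, SE 0.48, 0.00148), the allantoin catabolism gene DAL3 (-3.52, SE 0.50, 0.00218) and YEL045C (-3.61, SE 0.80, 0.0286) were also lower.

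Of the lists, 9 passed camera for translation efficiency at the preset correlation. With an estimated correlation none passed: adjusted p = 0.411 with an estimated correlation for tRNA synthetases, chaperones, glycolysis and sulfur and methionine genes, 0.462 for the vacuolar ATPase, 0.845 for translation factors and mitochondrial ribosomal proteins, 0.802 for the citric acid cycle and 0.878 for ribosome biogenesis. Aminoacyl tRNA synthetases (5 higher and 0 lower of 17, 7 adjusted over the list alone, median 0.64, camera adjusted p = 1.91e-06) included CDC60 (1.47), THS1 (1.07) and the valyl enzyme gene VAS1 (1.00). Chaperones (6 higher and 0 lower of 28, 13 adjusted over the list alone, 0.59, 3.15e-05) included HSP60 (1.11), the mitochondrial chaperonin gene, SSA2 (1.14), which shares sequence with SSA1, and HSP30 (2.02). Glycolysis genes (5 higher and 0 lower of 22, 8 adjusted over the list alone, 0.46, 5.15e-05) included the phosphofructokinase gene PFK1 (1.37), the hexokinase gene HXK2 (1.54) and TDH2 (1.39), uncertain beside its paralogs. Sulfur and methionine genes (4 higher and 0 lower of 24, 7 adjusted over the list alone, 0.60, 0.000468) included MET8 (1.38), the S-adenosylmethionine synthetase gene SAM1 (1.11), uncertain beside SAM2, and CYS4 (0.90). The vacuolar ATPase (0 called of 13, 3 adjusted over the list alone, 0.57, 0.00626), translation factors (0 of 37, 0 adjusted over the list alone, 0.34, 0.0196) and ribosome biogenesis (0 of 48, 0 adjusted over the list alone, 0.33, 0.0258) passed as lists without a called gene. The tricarboxylic acid and glyoxylate cycles (1 higher of 13, 2 adjusted over the list alone, 0.38, 0.0232) included the citrate synthase gene CIT2 (1.36), and mitochondrial ribosomal proteins (1 higher and 1 lower of 72, 2 adjusted over the list alone, -0.16, 0.0449) MRPL36 (-0.91) and RSM19 (1.28), whose coding length is 276 and 390 bases. Without 1 library 5 of the 9 lists lost their call, namely mitochondrial ribosomal proteins (0.210 without S. paradoxus RNA-seq replicate 2), ribosome biogenesis (0.202 without S. cerevisiae Ribo-seq replicate 1), translation factors and the citric acid cycle (0.124 and 0.0881 without S. paradoxus Ribo-seq replicate 2) and the vacuolar ATPase (0.0745 without S. paradoxus RNA-seq replicate 1). Mitochondrial ribosomal proteins also did not pass once the trend of each column on coding length was removed (camera adjusted p = 0.0505). That test was camera on z-scores of the gene tests in place of counts, which gave a camera adjusted p of 0.0197 before the removal. Of the 25 named genes 10 passed without each library, KNS1, YPL216W, HEF3, YOL014W, TEC1, DAL3, FLR1, CDC60, PFK1 and HXK2, and the highest value of the others was that of CYS4 (adjusted p = 0.195 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, without S. cerevisiae RNA-seq replicate 2). Lists that did not pass and whose median, mean and test differed in sign were oxidative phosphorylation, hexose transporters, oxidative stress and meiosis.

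Genes that differed in both mRNA and occupancy numbered 1201, of which 1174 went the same way and 27 the opposite way, with 741 expected if the calls were independent. Of 124 genes that differed in both mRNA and translation efficiency, 103 (83.1%, exact binomial 95% interval 75.3 to 89.2) had opposite directions, as KNS1 and CDC60 did. When the called translation efficiency differences were given to random genes in simulated counts, 57.7% opposed, with 72.3% in the highest of 20 draws. The share observed fell below that highest draw, to 63.0% without S. cerevisiae RNA-seq replicate 2, 68.3% without S. paradoxus Ribo-seq replicate 2 and 69.4% without S. cerevisiae Ribo-seq replicate 1. The count of 103 was 17 without S. cerevisiae RNA-seq replicate 2 and 474 without hybrid RNA-seq replicate 2, and each library but S. paradoxus RNA-seq replicate 2 and S. paradoxus Ribo-seq replicate 1 moved it over 1.5 times. The noise-free variance of occupancy ratios was 0.940 times that of mRNA ratios (0.890 to 0.991) over 4828 genes, with SDs of 0.813 for occupancy, 0.839 for mRNA and 0.499 for translation efficiency. The noise-free correlation of mRNA and translation efficiency ratios across genes was -0.348 (-0.387 to -0.307). Across 4786 genes mRNA and occupancy ratios correlated with Pearson's r of 0.79 and Spearman's rho of 0.73.

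**Figure D1:**
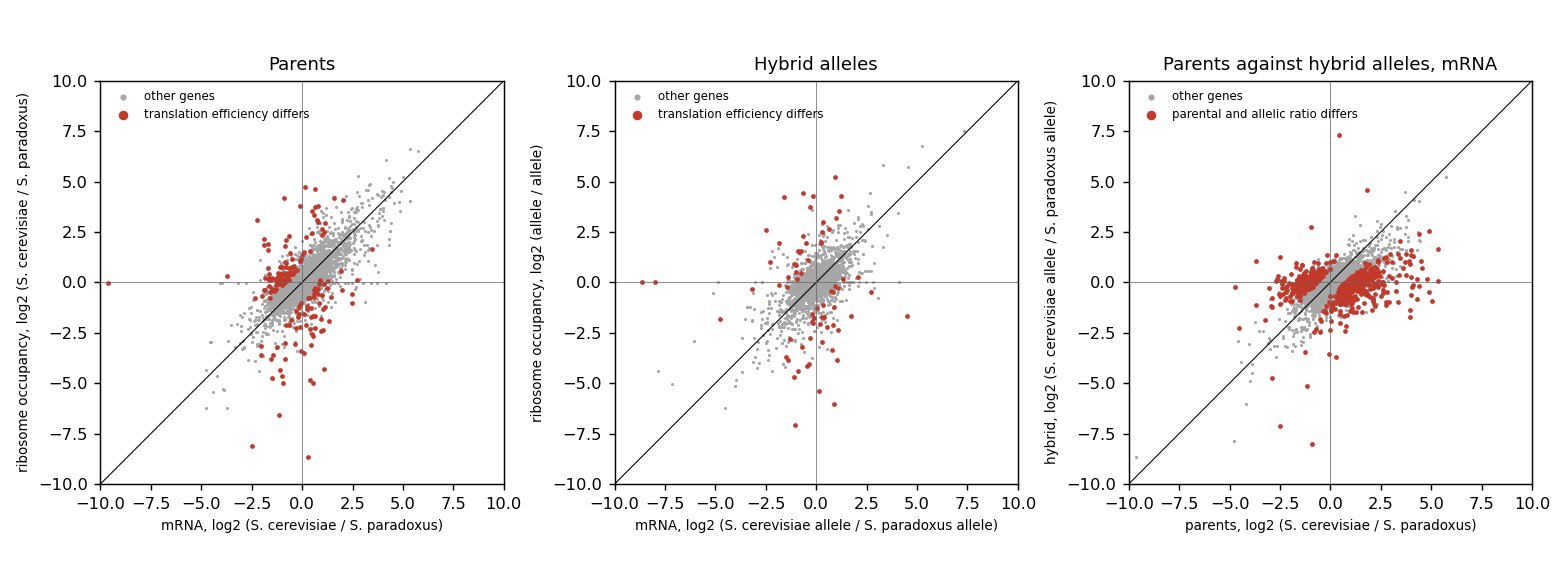
Log2 ratios (S. cerevisiae over S. paradoxus) of each tested gene, with mRNA against occupancy in the parents and in the hybrid alleles and parental against allelic mRNA. Red points mark the 179 and 71 genes whose translation efficiency differed in parents and alleles, and the 640 genes whose parental and allelic mRNA ratio differed.

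Between the 2 alleles of the hybrid, which share 1 cell, ADH2, CTR3 and RTA1 differed in the same direction as between the species. No functional list passed camera for allelic mRNA, with or without the library as a block. The S. cerevisiae alleles of ADH2, TIR3 and ICL2 gave most of the mRNA of these genes, and the S. paradoxus alleles most of that of PDR18, CTR3 and CDA1. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 668 genes differed (13.0%, 297 higher and 371 lower for the S. cerevisiae allele, 362 at least 2-fold), and with the library as a block 2124 (1146 and 978). With the random library effect, added after the values were seen, 2484 genes differed between the alleles and 2340 between the parents, so that which comparison held more calls depended on the fit. Each of the 24 named genes passed without each library.

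ADH2 had 456 ± 10.7 CPM from the S. cerevisiae allele and 12.2 ± 3.88 from the S. paradoxus allele (5.23, SE 0.29, adjusted p = 2.94e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for the alleles that follow, library block 7.68e-09). The cell wall mannoprotein gene TIR3 (IX, 333727 to 334536) had 163 ± 7.11 and 6.86 ± 0.407 CPM (4.56, SE 0.29, adjusted p = 7.48e-07). YJR096W (X, 611195 to 612043) had a ratio of 4.05 (SE 0.26, 7.48e-07), the 2-methylisocitrate lyase gene ICL2 3.30 (SE 0.36, 9e-05) and YHR033W 2.86 (SE 0.46, 0.00131). In the other direction the ABC transporter gene PDR18 (XIV, 765375 to 769376) had a ratio of -4.77 (SE 0.39, 1.07e-05). CTR3 had 6.89 ± 1.13 and 158 ± 6.63 CPM (-4.51, SE 0.30, 1.01e-06) and RTA1 a ratio of -3.96 (SE 0.36, 1.98e-05). CDA1, a chitin deacetylase gene of the spore wall, had -3.71 (SE 0.43, 0.000179), and NGL3 -3.53 (SE 0.40, 0.000143) with a parental ratio of -0.06. From the lists, RPL7A (-1.15), SPB4 (-0.69), MRPL28 (-1.07), TDH1 (-2.20), the sulfate transporter gene SUL1 (-2.36), the oxidoreductase gene OYE3 (-2.92), the pheromone pathway G protein gene GPA1 (-1.81) and the mating-type endonuclease gene HO (-2.73) were lower for the S. cerevisiae allele. ICL1 (2.72), the sterol desaturase gene ERG3 (1.35), the lysine synthesis gene LYS9 (1.34), HSP31 (2.55), the galactose repressor gene GAL80 (1.37) and the meiosis inducer gene IME1 (2.55) were higher. RPL7A and TDH1 counts are uncertain beside their paralogs. The ratio of HO rests on few RNA-seq counts, 4 and 3 for the S. cerevisiae allele and 24 and 25 for the S. paradoxus allele.

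Camera called 0 of the 26 lists for allelic mRNA and 0 for allelic translation efficiency, with 1 and 2 lists at an unadjusted p under 0.05 and 0 and 0 by fry. With the library as a block, a test added after the values were seen, it called 0 and 0, with 3 and 1 lists at an unadjusted p under 0.05 and smallest adjusted p of 0.296 and 0.321. The smallest adjusted p was 0.667 for mRNA, shared by phosphate and zinc uptake (2 higher and 0 lower of 17), amino acid synthesis (10 higher and 5 lower of 49, 21 and 13 with the library block) and haploid and mating genes (1 higher and 6 lower of 20). For translation efficiency it was 0.277, for oxidative stress (0 higher and 2 lower of 19). Cytosolic ribosomal proteins had 2 higher and 5 lower of 116 in allelic mRNA, and 47 and 16 with the library block. Median, mean and test differed in sign in allelic mRNA for the tricarboxylic acid and glyoxylate cycles, ergosterol synthesis, the cell wall and stationary-phase genes. They did so in allelic translation efficiency for ergosterol and amino acid synthesis, chaperones, the proteasome and haploid and mating genes.

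**Figure D2:**
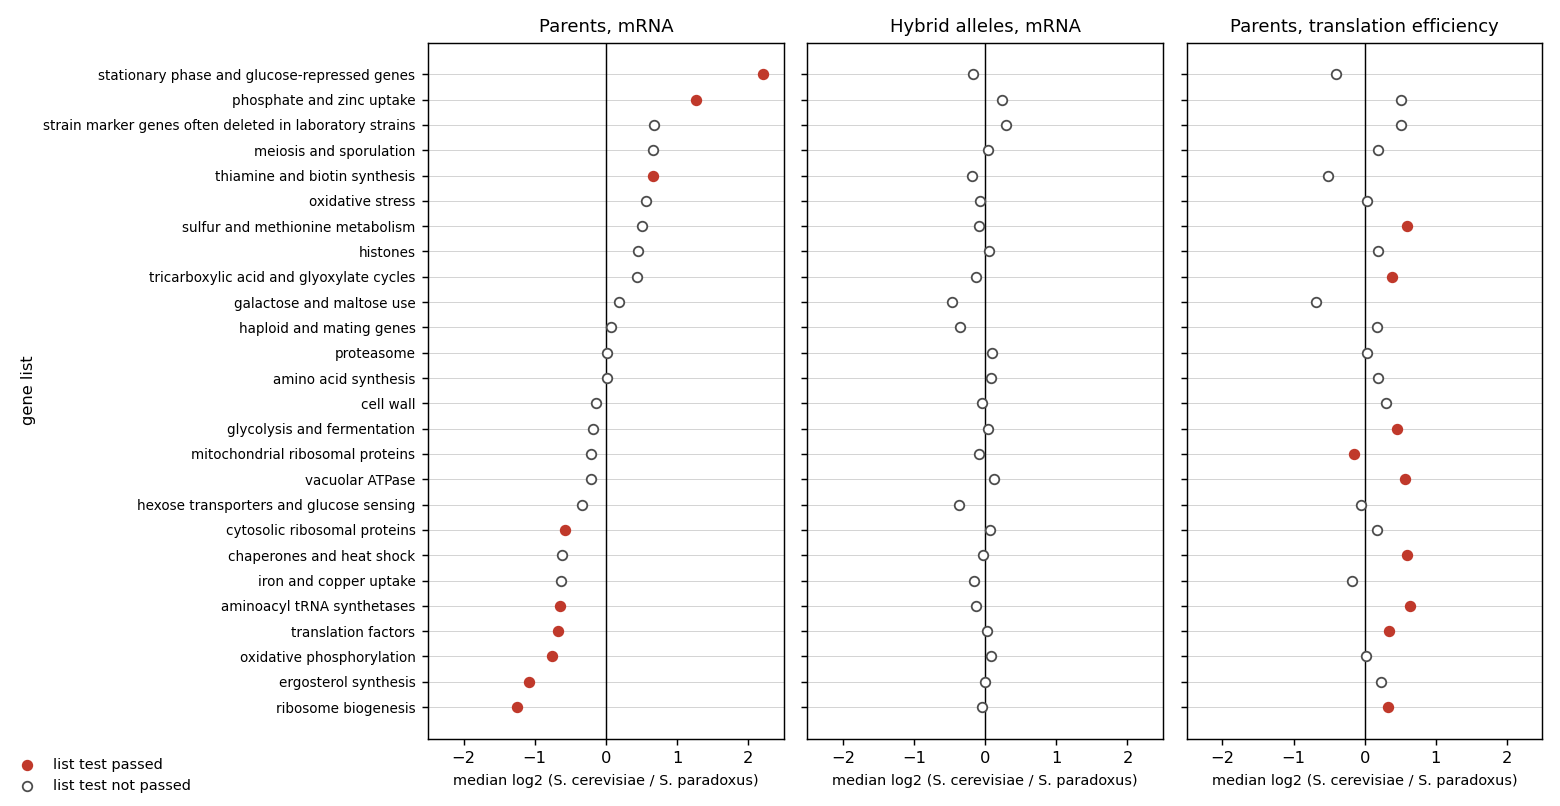
Median log2 ratio (S. cerevisiae over S. paradoxus) of each gene list for mRNA in the parents, mRNA of the hybrid alleles and translation efficiency in the parents, with filled points for lists that passed camera. In parental mRNA the medians ran from -1.24 for ribosome biogenesis to 2.21 for stationary-phase and glucose-repressed genes, and no list passed for the alleles.

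In translation efficiency the alleles of YOL014W, HEF3, YEL045C and YPL216W differed in the same direction as in the parents. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 451 genes differed in occupancy (211 higher, 240 lower) and 71 in translation efficiency (34 higher, 37 lower, median size 2.43), or 1464 and 426 with the library as a block. Without a hybrid Ribo-seq library occupancy gave 134 and 110 genes and translation efficiency 11 and 14. Without hybrid RNA-seq replicate 1 these were 984 and 147, and without replicate 2 occupancy gave 980. HEF3 had a ratio of 3.01 (SE 0.40, adjusted p = 0.0016, library block 0.000281), PDR18 2.95 (SE 0.59, 0.0247), RRG8 2.85 (SE 0.64, 0.0451), PHO3 2.44 (SE 0.49, 0.0272) and the urea amidolyase gene DUR12 2.38 (SE 0.53, 0.0451). The S. cerevisiae allele of BRE4 (IV, 38867 to 42244) had 126 ± 51.8 CPM in mRNA and 7.11 ± 0.293 in occupancy, and the S. paradoxus allele 165 ± 50.3 and 119 ± 3.68 (-3.68, SE 0.40, 0.000342, library block 2.39e-06). YOL014W had a ratio of -3.41 (SE 0.27, 2.8e-05, library block 1.41e-05), the peroxisomal gene DCI1 -3.26 (SE 0.39, 0.000878), YEL045C -3.70 (SE 0.81, 0.0407) and ICL1 -3.18 (SE 0.70, 0.0407). Of these 10 genes BRE4, YOL014W and DCI1 passed without each library, while HEF3 reached an adjusted p of 0.0629 without hybrid Ribo-seq replicate 1 and PDR18 0.578, the highest of the others, without replicate 2.

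In the alleles 233 genes differed in both mRNA and occupancy, 226 of them the same way (58.4 expected if independent), and 948 and 909 with the library block. Opposite directions of mRNA and translation efficiency were found in 30 of 40 genes (75%, 58.8 to 87.3), and in 258 of 307 (84.0%, 79.5 to 88.0) with the block. Called differences given to random genes in simulated counts opposed in 63.9% on average and in 100% in the highest of 20 draws, so the share of 75% lay within the simulated range. The count of 30 fell to 3 without either hybrid Ribo-seq library, was 19 and 18 without S. cerevisiae Ribo-seq replicate 1 or 2, and reached 78 without hybrid RNA-seq replicate 1. The noise-free variance of occupancy was 1.10 times that of mRNA (1.01 to 1.2) over 4819 genes, with SDs of 0.519 and 0.493. The noise-free correlation of mRNA and translation efficiency ratios was -0.314 (-0.379 to -0.253). Across 4786 genes mRNA and occupancy ratios of the alleles correlated with an r of 0.67 and a rho of 0.59.

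The parental and the allelic mRNA ratio differed for 10 of the 26 lists by camera at the preset correlation, and all but ergosterol synthesis were lost at adjusted p = 0.327 to 0.487 with an estimated correlation. The lower mRNA of the ribosome biogenesis, ergosterol synthesis and oxidative phosphorylation lists in S. cerevisiae and its higher mRNA of the phosphate and zinc uptake and stationary-phase lists passed as lists between the parents and not between the alleles, though the parental calls were lost at adjusted p = 0.052 to 0.572 with an estimated correlation. ADH2 and CTR3 differed in the same way in parents and alleles. YHB1, HXT2 and ZRT1 differed in opposite directions. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the parental and the allelic ratio differed for 640 genes in mRNA (356 up and 284 down for the parental minus the allelic ratio, 491 at least 2-fold), for 360 in occupancy (237 and 123) and for 0 in translation efficiency. The balance in mRNA turned with the scaling, at 306 up and 337 down with RLE, 425 and 506 with DESeq2, and 397 and 253 with shared scaling of the alleles. For translation efficiency 241 genes had an unadjusted p under 0.05, DESeq2 called 10, the random library effect 2 and a replicate block 1, and 2 and 3 passed without hybrid RNA-seq replicate 1 or 2. With the random library effect 1483 genes passed in mRNA and 800 in occupancy. Without 1 library the mRNA count ranged from 198 (without S. cerevisiae RNA-seq replicate 2) to 1210 (without hybrid RNA-seq replicate 1) and the occupancy count from 89 (without hybrid Ribo-seq replicate 2) to 1069 (without hybrid RNA-seq replicate 1), and each hybrid library moved both counts over 1.5 times, as did both S. cerevisiae RNA-seq libraries and S. paradoxus RNA-seq replicate 1 the first and the 4 parental Ribo-seq libraries the second.

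YHB1 (VII, 959904 to 961103), the nitric oxide detoxifying flavohemoglobin gene, had 1224 ± 216 and 80.5 ± 9.37 CPM in the parents and 181 ± 31.3 and 466 ± 2.11 for the alleles, a difference between the ratios of 5.29 (SE 0.27, adjusted p = 2.2e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for the differences that follow). SPL2 had 178 ± 38.2 and 172 ± 44.5 CPM for the alleles (5.31, SE 0.40, 8.04e-06), and PHM8 (5.34, SE 0.49, 5.4e-05), the stress gene HSP12 (5.66, SE 1.08, 0.00619) and BDH2 (5.93, SE 1.37, 0.0156) also differed. CYC1 had 426 ± 69.6 and 344 ± 8.55 CPM for the alleles (-2.92, SE 0.28, 5.67e-05). The zinc transporter gene ZRT1 had 74.0 ± 6.58 and 144 ± 16.6 CPM in the parents and 455 ± 116 and 68.4 ± 15.1 for the alleles (-3.69, SE 0.35, 5.67e-05). The hexose transporter gene HXT2 (-3.79, SE 0.42, 0.000237), FRE4 (-4.51, SE 0.54, 0.000332) and PRM7 (-4.75, SE 0.72, 0.00156) were in the same direction.

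Of the lists, 10 passed camera for the difference between the parental and the allelic mRNA ratio, and each did so without each library. With an estimated correlation the 9 other than ergosterol synthesis did not pass: adjusted p = 0.451 with an estimated correlation for stationary-phase genes, thiamine and biotin and the synthetases, 0.437 for phosphate and zinc and oxidative stress, 0.425 for ribosome biogenesis, 0.487 for cytosolic ribosomal proteins and 0.327 for translation factors and oxidative phosphorylation. Ribosome biogenesis had a median difference of -1.22 (0 up and 21 down of 48, 42 adjusted over the list alone, camera adjusted p = 3.41e-18), with NSR1 (-1.97), NOC4 (-1.59) and UTP5 (-1.48). Ergosterol synthesis had -0.99 (0 up and 16 down of 24, 19 adjusted over the list alone, 1.04e-13), with CYB5 (-2.75), ERG3 (-1.51) and the mevalonate decarboxylase gene MVD1 (-1.56), and was the only list in any comparison that passed with an estimated correlation (adjusted p = 0.0139 with an estimated correlation). Cytosolic ribosomal proteins had -0.62 (0 up and 4 down of 116, 0 adjusted over the list alone, 3.77e-11), with RPS14B (-0.95), RPL8B (-0.74) and RPL3 (-0.78), the first 2 uncertain beside duplicates. The median of this list was -0.38 without S. paradoxus RNA-seq replicate 1. In it the S. paradoxus RNA-seq replicates differed by a median of -0.44 (replicate 2 minus replicate 1). Translation factors had -0.72 (0 up and 10 down of 37, 21 adjusted over the list alone, 3.00e-09), with HYP2 (-1.62), TIF6 (-0.95) and YEF3 (-1.74). Oxidative phosphorylation had -0.69 (0 up and 11 down of 32, 16 adjusted over the list alone, 1.16e-08), with CYC1, the cytochrome oxidase gene COX5A (-1.51) and RIP1 (-1.46). Aminoacyl tRNA synthetases had -0.62 (0 up and 4 down of 17, 9 adjusted over the list alone, 0.000238), with CDC60 (-1.17), VAS1 (-0.96) and GRS1 (-0.73).

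Stationary-phase and glucose-repressed genes had a median difference of 1.51 (7 up and 0 down of 24, 9 adjusted over the list alone, camera adjusted p = 9.72e-05), the same with 3 members set to a floor of 3 counts per library, and included HSP12, NTH1 (2.00) and SOL4 (4.31). Phosphate and zinc uptake had 0.98 (8 up and 2 down of 17, 11 adjusted over the list alone, 9.72e-05), with SPL2 and PHO84 (3.22) up. The zinc transporter gene ZRT1 (-3.69) in this list was down. PHO84 had 1889 ± 859 and 1841 ± 770 CPM for the alleles. Thiamine and biotin synthesis had 0.99 (3 up and 0 down of 15, 4 adjusted over the list alone, 0.000771), with PHO3 (3.30), BIO2 (1.76) and the thiazole synthesis gene THI4 (2.06). Oxidative stress had 0.52 (6 up and 0 down of 19, 8 adjusted over the list alone, 0.00163), with GPX1 (2.07), the glutathione reductase gene GLR1 (0.87) and the glutaredoxin gene GRX2 (1.16). From the lists that did not pass, MET17 (2.58), the chaperone gene SSE2 (2.44), RME1 (3.75) and the succinyl-CoA ligase gene LSC2 (1.17) were up and TIR3 (-2.76), HXK2 (-1.29) and the arginine synthesis gene ARG8 (-1.12) down. Median, mean and test differed in sign for glycolysis, hexose transporters and chaperones. The hybrid RNA-seq replicates differed from each other in some of the same lists, with a median log2 difference (replicate 2 minus replicate 1) of -0.72 for ribosome biogenesis, -0.41 for cytosolic ribosomal proteins, 0.79 for phosphate and zinc uptake, 0.73 for thiamine and biotin synthesis and 0.91 for stationary-phase genes, and 0.21 for ergosterol synthesis. Of the 43 named genes 32 passed without each library, and RPL3, THI4, GRS1, RPL8B, RPS14B, BDH2, GRX2, VAS1, GLR1, TIF6 and YEF3 did not, with the highest adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at THI4 (0.141 without S. cerevisiae RNA-seq replicate 2).

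**Figure D3:**
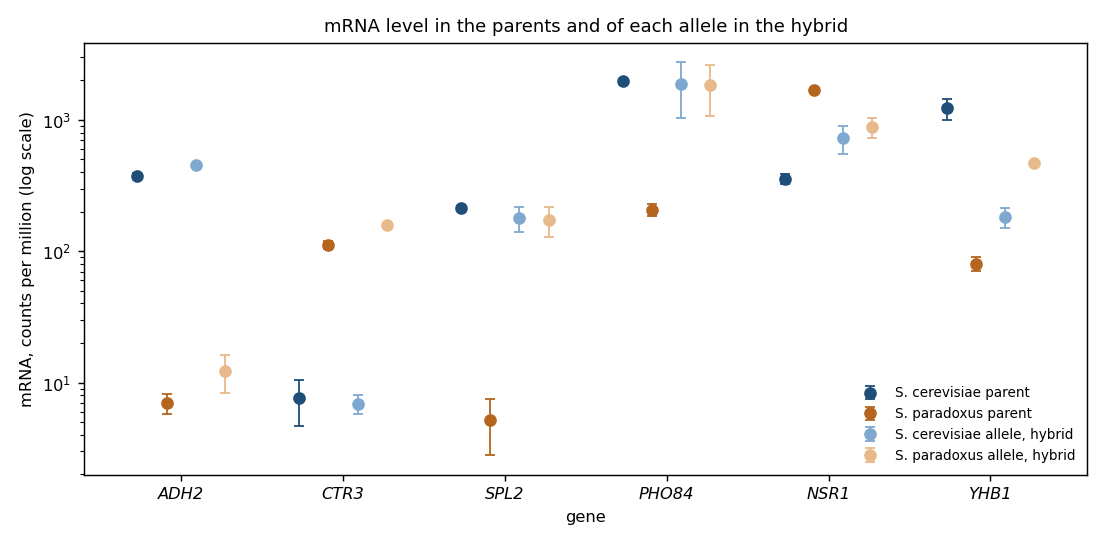
mRNA in CPM (log axis, points for libraries' mean, bars for SD, n = 2) of ADH2, CTR3, SPL2, PHO84, NSR1 and YHB1 in the parents and for the hybrid alleles. ADH2 and CTR3 differed in the same direction in parents and alleles, SPL2, PHO84 and NSR1 differed more between the parents than between the alleles, and YHB1 differed in opposite directions.

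By the combination of the 3 mRNA tests, 397 genes differed between parents and alleles alike without a called difference between the ratios. This is the pattern of an allelic, or cis, difference, and ADH2, CTR3 and RTA1 had it. Another 505 differed between the parents and between the ratios without a call between the alleles, among them SPL2, PHO84, CYC1 and CYB5. This is the pattern of a trans difference, which a difference in growth state between cultures could also give. Each class rests on a test that did not pass. In simulated counts the test between the ratios recovered 1.49% of 1.5-fold and 11.9% of 2-fold changes, so a missing call is weak evidence of no difference. With the library as a block the alleles of CYC1 differed by 0.33 (adjusted p = 0.00748 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and those of NSR1 by -0.27 (0.00536). A difference in all 3 was found for 43 genes with the same and 24 with the opposite direction, in 53 genes the alleles and the ratios differed without a parental difference, 2694 passed in none and 1442 were ambiguous. With the random library effect the first 2 classes held 820 and 730 genes. In occupancy they held 278 and 273. Calls for parents and alleles overlapped in 464 genes for mRNA (440 the same way, 291 expected if independent), 326 for occupancy (312, 149 expected) and 38 for translation efficiency (all 38, 2.46 expected). Across 4786 genes parental and allelic ratios correlated with an r of 0.50 for mRNA, 0.52 for occupancy and 0.55 for translation efficiency.

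When the alleles were summed, most genes were not called outside the range of the parents. For mRNA this test recovered 4.48% of 1.5-fold changes in simulated counts, so small departures could be missed. The hybrid stood above both parents for the sodium-phosphate cotransporter gene PHO89, TIR3 and the mitochondrial citrate carrier gene CTP1. It stood below both for the pyrimidine synthesis gene URA1 and the cytosolic malate dehydrogenase gene MDH2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment hybrid mRNA differed from S. cerevisiae for 1310 genes and from S. paradoxus for 1325, and 100 genes lay outside the parental range, 70 above and 30 below. In occupancy 17 did, 7 above and 10 below, 8 of them in both assays and in the same direction (0.330 expected if independent). DESeq2 gave 20 above and 12 below in occupancy, the reverse balance, which also turned without S. paradoxus Ribo-seq replicate 2 and without each hybrid library. Simulated hybrids at the mean of the parents gave on average 2.3 genes in mRNA and 1.4 in occupancy. These draws gave a gene the same dispersion in every group. The hybrid RNA-seq replicates varied more, with SDs of the log2 replicate difference of 0.623 and 0.614 for the alleles. In RNA-seq of S. cerevisiae and S. paradoxus these SDs were 0.209 and 0.414. The draws can therefore understate the count that noise gives in mRNA. The count of 100 was 1030 without hybrid RNA-seq replicate 1 and 41 without replicate 2, 19 and 22 without S. cerevisiae RNA-seq replicate 1 or 2, and 65 and 48 without S. paradoxus RNA-seq replicate 1 or 2. The excess above both parents was lost without S. paradoxus RNA-seq replicate 1 (33 above and 32 below) and without hybrid RNA-seq replicate 1 (501 and 529) or 2 (18 and 23). The count of 17 was 64 and 57 without hybrid RNA-seq replicate 1 or 2, 8 without hybrid Ribo-seq replicate 2, 11 without S. cerevisiae Ribo-seq replicate 1 and 10 without S. paradoxus Ribo-seq replicate 1.

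PHO89 had 654 ± 481 CPM in the hybrid, 91.9 ± 55.0 in S. cerevisiae and 49.0 ± 24.8 in S. paradoxus, 2.83 above the nearer parent on the log2 scale (adjusted p = 0.00649 and 0.00239 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with replicates far apart. The proline transporter gene PUT4 was 1.63 above (34.8 ± 27.4 CPM in the hybrid, 4.60 ± 2.03 and 11.2 ± 2.93 in the parents). TIR3 was 1.55 above in mRNA (83.6 ± 2.38 against 28.5 ± 4.25 and 8.18 ± 3.18 CPM) and 1.59 above in occupancy (184 ± 4.98 against 61.3 ± 15.6 and 9.47 ± 0.506). URA1 had 161 ± 43.9 CPM in the hybrid, 510 ± 66.5 in S. cerevisiae and 344 ± 12.3 in S. paradoxus (-1.09), and the kinetochore gene NUF2 23.8 ± 13.6 against 58.3 ± 1.55 and 49.5 ± 9.10 (-1.06). In occupancy CTP1 was 1.56 above (63.1 ± 2.54 against 10.9 ± 1.47 and 21.4 ± 1.27 CPM) and the alpha-factor receptor gene STE2, which a/alpha diploids repress, 1.57 above (8.69 ± 0.685 against 1.85 ± 0.128 and 2.91 ± 0.110). MDH2 was lower (14.3 ± 3.51 against 115 ± 0.951 and 46.8 ± 1.02 CPM, -1.70), as was NFG1 (1.05 ± 0.343 against 4.37 ± 0.159 and 13.1 ± 0.661, -2.04). HMLALPHA1, a silent mating-type gene whose counts are uncertain beside the active copy, was also below both parents and had at most 1 count in every hybrid column. TIR3 in both assays, URA1 in mRNA and CTP1, MDH2 and NFG1 in occupancy stayed outside the range without each library. The higher adjusted p of the comparisons with each parent rose above 0.05 for PHO89 without S. cerevisiae RNA-seq replicate 2 (0.0688), STE2 without S. paradoxus Ribo-seq replicate 1 (0.0551), and PUT4 without S. paradoxus RNA-seq replicate 1 (0.18) or 2 (0.0854) or hybrid RNA-seq replicate 2 (0.441). It did so for NUF2 without either S. cerevisiae RNA-seq library (0.0587 and 0.0542), either S. paradoxus one (0.0512 and 0.127) or hybrid RNA-seq replicate 2 (0.0645). HMLALPHA1 lost its call in mRNA without either S. cerevisiae RNA-seq library (0.0592 and 0.107) or hybrid RNA-seq replicate 2 (0.0802), and in occupancy without S. cerevisiae Ribo-seq replicate 1 (0.209) or either hybrid Ribo-seq library (0.112 and 0.106).

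No chromosome stood apart as a whole. Relative to the median of all genes, median ratios per chromosome ran from -0.07 to 0.13 for parental mRNA, from -0.07 to 0.19 for parental occupancy, from -0.06 to 0.07 for allelic mRNA and from -0.06 to 0.03 for allelic occupancy.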

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

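Among the tests below, those of gene length for all 3 patterns, of scaling for the parental lists and of RNA-seq noise, and the simulated translation efficiency differences at random genes, were chosen only after the result was seen. The results collected here drew attention because the parents and the hybrid alleles differed in the same species contrast, by an interaction test. The mRNA ratio of the parents differed from that of the alleles for 640 genes and the occupancy ratio for 360 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In 24 genes the mRNA ratio passed in opposite directions. YHB1, a nitric oxide detoxifying flavohemoglobin, had a parental log2 ratio of 3.93 and an allelic ratio of -1.36, and the hexose transporter HXT2 had -2.51 and 1.28. The zinc transporter ZRT1 had -0.96 and 2.74, the phosphoglycerate mutase homolog GPM2 0.75 and -2.42, and the asparagine synthetase ASN1 -1.40 and 0.85. These 5 were chosen after their values were seen.

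The median difference between the parental and the allelic mRNA ratio was -1.22 for ribosome biogenesis, -0.99 for ergosterol synthesis, -0.72 for translation factors, -0.69 for oxidative phosphorylation, and -0.62 for both cytosolic ribosomal proteins and aminoacyl tRNA synthetases. It was 1.51 for stationary-phase and glucose-repressed genes, 0.99 for thiamine and biotin synthesis, 0.98 for phosphate and zinc uptake and 0.52 for oxidative stress. With an estimated correlation 9 of the 10 calls were lost (adjusted p = 0.327 to 0.487 with an estimated correlation) and ergosterol synthesis passed (0.0139). At the preset correlation all 10 of the 10 lists kept their call and direction after each column's trend on coding length was removed, which argues against gene length as the cause. The calls after removal came from camera on z-scores of the gene tests, and the main calls from camera on counts. A shift of the scaling moves every gene of a column alike, and these medians went up in 4 of the 10 lists and down in 6. Camera compares a list with the other genes, so lists picked by it can have both signs with or without such a shift. The signs therefore decide nothing about scaling. A difference in growth state between cultures may contribute. Across 4143 genes outside the lists, the difference between the 2 hybrid RNA-seq replicates, which share 1 genotype, correlated with the parental mRNA ratio by 0.277 (95% bootstrap interval 0.242 to 0.314). This lay between the bounds set in advance, 0.1 and 0.3, so growth state and the strain difference that the design names cannot be told apart for these lists.

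The mRNA and translation efficiency ratios of the parents opposed each other in 103 of the 124 genes that passed in both. Noise in the RNA-seq libraries enters both ratios with opposite signs, but noise of single libraries drops out of covariances between replicates, and the correlation of the ratios from these was -0.348 (95% bootstrap interval -0.387 to -0.307) across 4828 genes, which argues against noise as the whole cause. Simulated counts with no translation efficiency difference called 0 genes for translation efficiency and so decided nothing. After removal of the trend on coding length the correlation of the noise-free ratios was -0.333 (-0.373 to -0.292), which argues against gene length as the whole cause. When the called translation efficiency differences were given to random genes in simulated counts, 57.7% of genes passing in both opposed, with 72.3% in the highest draw, against 83.1% observed. The observed share was inside the range of these draws, at 63.0%, 68.3% and 69.4%, without S. cerevisiae RNA-seq replicate 2, S. paradoxus Ribo-seq replicate 2 or S. cerevisiae Ribo-seq replicate 1, so this comparison excludes nothing. Opposing translation in the strains stays a hypothesis, and any step of preparation that affected RNA-seq and Ribo-seq unequally by species was not tested and could lead to the same pattern.

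The hybrid RNA-seq replicates stood apart from each other, with 358 of 4786 genes over 2-fold between them, against 13 in S. cerevisiae and 68 in S. paradoxus. Ribosome biogenesis genes had a median difference of -0.72 (replicate 2 minus replicate 1), cytosolic ribosomal proteins -0.41, hexose transporters 1.14, galactose and maltose genes 1.13, and stationary-phase genes 0.91. The difference correlated with log2 coding length by 0.151, which argues against gene length as the cause. All columns were also thinned to the lowest total, 6116133 counts. The replicates of the S. cerevisiae allele then correlated by 0.951, against 0.993 and 0.979 in the parents. Before thinning the replicates of this allele held 6932791 and 6456613 counts and also correlated by 0.951. Thinning removed few counts, so the correlation could hardly move and the test decided nothing about depth. No biological explanation was tested, since the design names no difference between replicates, and a difference between cultures or preparations could remain.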

How the results depend on the processing

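The random library effect, the parental fit and hybrid block for the opposing counts, zeros raised to 1, the removal of the length trend and list tests with the library block were chosen after the values were seen. DESeq2 moved parental translation efficiency to 371, allelic translation efficiency to 128, the parent minus hybrid difference to 609 in occupancy and 10 in translation efficiency, opposing genes to 231 in parents and 58 in alleles, and occupancy outside the parental range to 32. Replicate numbers were shared by 26 pairs of groups with correlations of -0.07 to 0.38, over 0.1 in 18 and not in every pair, so they were not taken to pair libraries, apart from the alleles of 1 library. Between strains these correlations were 0.26 to 0.36 in RNA-seq and 0.09 to 0.14 in Ribo-seq. Spread that RNA-seq libraries of the same number share may therefore remain in the main tests. With replicate number as a block, parental translation efficiency gave 306, parent minus hybrid 1023 for mRNA, 601 for occupancy and 1 for translation efficiency, opposing genes in parents 194 and occupancy outside the range 32 (20 above and 12 below, against 7 and 10). The near balance of parental mRNA (1129 higher and 1116 lower) was 1060 and 1228 with RLE and 1103 and 1311 with DESeq2. Without hybrid RNA-seq replicate 1 the balance also turned for parental occupancy (1230 and 1260), allelic mRNA (428 and 409) and allelic occupancy (501 and 483), and without replicate 2 for allelic occupancy (503 and 477) and parent minus hybrid mRNA (512 and 537). A block within strain gave 341 and 198 for parental translation efficiency and opposing genes. With the hybrid library as a block, the alleles gave 2124 for mRNA, 1464 for occupancy, 426 for translation efficiency and 258 opposing genes. Parental libraries alone gave 572 for translation efficiency and 370 opposing genes. The random library effect gave 2484, 1814 and 812 for the alleles, 1483, 800 and 2 for parent minus hybrid, and 503 opposing genes in the alleles. A minimum fold of 1.5 left 66 genes with hybrid mRNA outside the range. The variance ratio of the parents was 0.992 at a mean count of at least 50 and 0.884 with a pseudocount of 5, and that of the alleles 1.01 with a pseudocount of 5. With an estimated correlation 0 lists passed for parental mRNA, 0 for parental translation efficiency and 1 for parent minus hybrid mRNA, and with fry 17 lists passed for parental mRNA and 5 for parental translation efficiency. The cause of these shifts was not tested. By construction, blocks and the random effect remove spread between libraries, and the parental fit leaves out the hybrid columns with their spread.

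Leaving out 1 library, with the lone library assumed to vary like the other groups, gave 1352 to 3091 genes for parental mRNA, 1027 to 2491 for parental occupancy, 56 to 722 for parental translation efficiency, 110 to 984 for allelic occupancy and 11 to 147 for allelic translation efficiency. Parent minus hybrid gave 198 to 1210 genes for mRNA, 89 to 1069 for occupancy and 0 to 3 for translation efficiency. Opposing genes ranged from 17 to 474 in parents and 3 to 78 in alleles, and genes outside the parental range from 19 to 1030 in mRNA and 8 to 64 in occupancy. The highest counts came without a hybrid RNA-seq library. Allelic mRNA, at 473 to 837, stayed within 1.5 times its count.

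Of 420 results for the 28 lists that passed, 372 kept call and direction and 48 lost the call, 27 of them with an estimated correlation, 7 with fry and 14 without 1 library. Of 3612 results for the 160 calls of genes named by the fixed rule, hybrid totals included, 3379 kept both and 233 lost the call. None of either reversed. RLE scaling shifted the median of all genes by at most 0.06. At this depth and n = 2, 0% of simulated 1.5-fold changes in parental translation efficiency were recovered among 5145 genes.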

Other observations

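The list tests on occupancy, with and without the library block, the tests of coding length and the genes of this part other than TIR3, CTP1, URA1 and HMLALPHA1 were chosen only after the values were seen. No list was tested on the hybrid's totals. Genes whose total mRNA lay above both parents included LYS9 (hybrid minus nearer parent 0.98 on the log2 scale, 239 ± 7.01 CPM in the hybrid) and LYS4 (1.12, 314 ± 109), and the transcription factor gene RPN4 (-0.69, 101 ± 18.4) lay below both. In both mRNA and occupancy TIR3, CTP1, ZRT1 and LYS9 were above both parents and URA1, RIB4 and HMLALPHA1 below. RIB4, a riboflavin synthesis gene, was -0.77 from the nearer parent in mRNA and -1.02 in occupancy. TIR3, CTP1, LYS9 and RIB4 kept both calls without each library. LYS4 lost its call without S. cerevisiae RNA-seq replicate 1 (adjusted p = 0.053) and RPN4 without S. paradoxus (0.075) or hybrid RNA-seq replicate 2 (0.0581). ZRT1 lost it in mRNA without S. paradoxus (0.0915) or hybrid RNA-seq replicate 2 (0.0854) and in occupancy without S. paradoxus (0.116) or hybrid Ribo-seq replicate 1 (0.0643), and URA1 in occupancy without S. paradoxus (0.0568) or hybrid Ribo-seq replicate 2 (0.0905). Gene by gene, these calls passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment against each parent.

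For parental ribosome occupancy 13 of the 26 lists passed camera at the preset correlation and 0 with an estimated one. Of these 13, 6 had not passed for mRNA, namely sulfur and methionine and tricarboxylic acid cycle genes, mitochondrial ribosomal proteins (0.000939, adjusted p = 0.516 with an estimated correlation), iron and copper uptake (0.00151, 0.516), glycolysis (0.0101, 0.516), and strain marker genes (0.00117, 0.0889). The synthetases (0.870) and thiamine and biotin synthesis (0.427), which had passed for mRNA, did not pass. In the parents, ribosome biogenesis genes had a median occupancy ratio of -0.91 (0 higher and 33 lower of 48, camera adjusted p = 1.06e-09, adjusted p = 0.516 with an estimated correlation) and phosphate and zinc uptake genes 1.48 (11 higher and 3 lower of 17, 3.84e-07, adjusted p = 0.298 with an estimated correlation). Sulfur and methionine genes (14 higher and 1 lower of 24) had a median of 0.90 (0.000129, adjusted p = 0.298 with an estimated correlation), and tricarboxylic acid and glyoxylate cycle genes (11 higher and 0 lower of 13) 0.80 (0.000365, adjusted p = 0.488 with an estimated correlation). Between the hybrid alleles, oxidative stress genes (0 higher and 5 lower of 19) had a median of -0.23 (camera adjusted p = 0.00997, adjusted p = 1.00 with an estimated correlation) and strain marker genes (3 higher and 0 lower of 7) one of 0.81 (0.0208, adjusted p = 0.304 with an estimated correlation). With the library as a block both passed (0.00727 each), as did phosphate and zinc uptake genes (median 0.20, 0.016), and none of the 3 with an estimated correlation (adjusted p = 0.801 with an estimated correlation for each).

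Over 5 classes of coding length, from the shortest to the longest, the median mRNA ratio of the parents was -0.04, 0.13, 0.14, 0.03 and -0.27 and that of translation efficiency 0.08, -0.06, -0.05, 0.01 and 0.26, without a steady trend. In the longest class (1015 genes) the median occupancy ratio was 0.01 and the allelic mRNA ratio -0.04. The replicate difference of the S. paradoxus RNA-seq libraries correlated with log2 coding length by 0.347 across genes. After removal of the trend, 2372 genes passed for parental mRNA (2061 shared with the untreated call), 221 for parental translation efficiency (156 shared) and 760 for the difference between parental and allelic mRNA ratio (567 shared). List tests after removal used camera on z-scores of the gene tests, while the main list tests used counts. In this form the mitochondrial ribosomal protein list had a camera adjusted p of 0.0197 for translation efficiency before removal and 0.0505 after it. It lost its call, and the other 8 lists kept theirs.

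The silent mating-type gene HMLALPHA1, whose sequence is shared with the active alpha copy and whose counts are therefore uncertain, had 8 and 11 RNA-seq counts in S. cerevisiae and 83 and 44 in S. paradoxus. In the hybrid it had 1 and 0 for the S. cerevisiae allele and 1 and 1 for the S. paradoxus allele, and 1 in every Ribo-seq column. HMRA1 had 226 and 129 RNA-seq counts for the S. cerevisiae allele of the hybrid and 1 in all 4 columns of the S. paradoxus allele. A count of 1 was the lowest value that the columns of the S. paradoxus allele held. In the parents HMRA1 had 142 and 148 RNA-seq counts in S. cerevisiae and 113 and 62 in S. paradoxus.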
